A study of Mus musculus with 3 samples.

How the data were processed

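Next-generation Capture-C was applied to erythroid cells cultured from mouse fetal livers, harvested at embryonic day 12.5, that lacked the beta-globin enhancers HS2 and HS3 on both chromosomes. Capture-C is a chromosome conformation capture assay in which crosslinked chromatin is cut with a restriction enzyme and religated, and ligation products of chosen viewpoint fragments are enriched with oligonucleotides. Per the labels' protocols, cells were expanded for 6 days, selected for CD117, and induced to differentiate, with a 24 h time point. They were fixed with 2% formaldehyde for 10 min and the chromatin was cut with DpnII, with digestion above 70%. The labels place these samples at the late erythroid stage. Trim Galore, Bowtie2 and the genome build mm9 are named in the submitters' processing notes without versions. How ligation junctions were counted, which fragments were listed and which reads were filtered is not given in the sources used here.

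The deposited values are raw counts of reads per DpnII fragment of chromosome 7, the chromosome of the viewpoint. Only the Hbb profile was analysed here. The deposited table holds 3 count columns under a header of 1 cell, which names the genotype and 1 replicate. The 3 columns were therefore taken as the 3 samples of the only group, without a replicate number, and are called the first, the second and the third column by their order. The labels do not say that each sample came from a separate animal, so the spread between columns may in part be technical. Of the 48123 listed fragments, 10242 (21.3%) had 0 reads in all 3 columns, so the list was not made from these columns alone. The list covered 94.5% of the sequence within 100 kb of the viewpoint, 76.4% at 1 to 2 Mb and 25.6% at 10 to 20 Mb. Fragments that were not listed were treated as having no reads.

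The labels name Hbb-b1 as the viewpoint without a position. The viewpoint was placed at the centre of the unlisted stretch of at least 1.5 kb next to the fragment with the most reads. A second such stretch lay 13.9 kb away. Hbb-b1 has a near-identical copy, Hbb-b2, and whether reads of both were joined is not stated. The deposited profile carries the name HbbCombined, without a statement of what was combined. If 2 viewpoints were joined, distances from a single position hold only in part. The other stretch and the midpoint were tried as viewpoints.

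The gene table at hand is for GRCm38 and was used only for the order of genes, since its coordinates cannot be set beside mm9. The planned contacts of single Hbb genes, of olfactory receptor genes, of other neighbouring genes and of a list of distal erythroid genes were therefore not run, and no position was assigned to a gene. The planned window for the locus control region (LCR) beyond Hbb-y could not be placed either. It was replaced by 10 kb on each side of the footprint, defined as the longest run, in bp of listed fragments, without reads within 100 kb of the viewpoint. The side of the footprint, that of higher coordinates, was called the LCR side. That gene order and the known place of the LCR beyond Hbb-y also put the LCR there. The tests, distance ranges, window size, threshold and dispersion range of the decay, the shares, the comparison of sides and the contact peaks were fixed before the data were examined. The viewpoint rule, the LCR window, the search for the footprint within 100 kb on both sides, the flanks, mirror positions and fragment clusters, the number of distance bins and bootstrap draws, and the fold rule below were chosen after seeing the data.

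Fragments were assigned to windows by their midpoints. Densities are reads per kb per 100000 cis reads of the same column and are given as mean ± SD over the 3 columns. The expected density at a distance was a monotone curve (isotonic regression, scikit-learn 1.9.0) through 10 bins per decade of distance over both sides. For the LCR it was fitted without the LCR window, so at the distances of that window it rested mostly on the other side. The decay slope was a least-squares fit of log10 density on log10 distance from 5 kb to 10 Mb, with an interval from 2000 bootstrap draws of the bins. Contact peaks were 5 kb windows, 10 kb to 1 Mb away, whose summed reads exceeded the expectation in a one-sided negative binomial test with Benjamini-Hochberg adjusted p under 0.05. Its dispersion came from windows 200 kb to 10 Mb away, in which unlisted fragments also counted as having no reads. The rule for named items, fixed before the data were examined, took all Hbb genes, the 10 protein-coding genes within 1 Mb with the highest and the 10 with the lowest ratio of observed to expected reads, every gene of the distal list, and the 5 called windows with the highest ratio. Its gene parts could not be run and no window was called, so the rule named nothing. The windows named instead are the 5 highest among those at least 2-fold over expectation in every column, chosen after seeing the data. Sides of the viewpoint were compared with an exact sign-flip permutation test over 3 columns, which cannot give a p below 0.25. Intervals are 95% exact binomial or exact Poisson intervals and cover counting error only.

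The functions were tested on simulated data. A true slope of -1 was recovered as -1.00 and a 4-fold raised LCR window as 4.05. Both checks used Poisson counts from a power law on a complete grid of 180000 sites. They do not show how unlisted fragments, empty runs, extra spread or a difference between sides affect the estimates. In 396 simulated windows at the fitted dispersion, 4.5% of 3-fold, 16.5% of 5-fold and 60.3% of 20-fold raised windows were called. Alternatives were capping fragment counts at the 99.9th percentile, leaving out fragments under 100 bp, a power law or 1 side as expectation, other distance ranges and windows, and leaving out each column. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.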

Results

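The contacts of the beta-globin viewpoint were measured in 3 samples of 1 group, differentiated fetal liver erythroid cells with a homozygous combined deletion of HS2 and HS3. These are DNase-hypersensitive elements of the LCR, the distal enhancer cluster that drives beta-globin transcription in erythroid cells. The columns held 49433, 49247 and 37382 cis reads over 16859, 18536 and 13823 fragments. A count of 0 in a column allows up to 0.00607%, 0.00609% and 0.00803% of its reads. Over 196 windows of 5 kb within 1 Mb with at least 30 reads, chi-square per degree of freedom between columns was 1.73 to 2.92. The columns thus differed by more than the counting noise of independent reads, and whether duplicate reads add to this is not known. Their Spearman correlations across these windows, which are not independent replicates, were 0.73 to 0.78. Wild-type profiles were not analysed here, and the comparisons are between positions within the deletion profile.

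The first question was whether the profile carries the deletion that the labels name. The longest run of fragments without reads within 100 kb of the viewpoint was at chr7 111009378 to 111016071 (mm9). In the computation its side defined the LCR side, which is also where the gene order puts the LCR. It covered 14 adjoining fragments and 6694 bp, 33.2 to 39.9 kb from the viewpoint, and had 0 reads in each of the 3 columns. The 5 kb on each side of it predicted 2720, 2150 and 2007 reads for the 3 columns, and the distance curve predicted 1122 reads in all and at least 310 in each column. The fragment on its viewpoint side, 111009074 to 111009377, had 22 reads, and the fragment beyond it, 111016072 to 111016871, had 307 reads. It is called the footprint here. Within 1 Mb, runs without reads of 5913, 5854 and 5297 listed bp began at 110843327, 111444856 and 111438712, where distance predicted 123, 46.0 and 36.6 reads and flanks predicted 60.3, 4.05 and 6.45. Another run without reads, of 5226 listed bp, began at 110964839 on the other side, close to the viewpoint. There distance predicted 1502 reads and flanks predicted 6863, so an empty run with many predicted reads was not particular to the footprint. In the known order of the LCR, HS1 lies on the globin side of HS2 and HS3, and HS4 and the later elements lie beyond them.

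The sequence on either side of the footprint was contacted more often than its distance predicted. The 10 kb on the viewpoint side had a density of 442 ± 42.8 reads per kb per 100000 cis reads (SD, n = 3), and the 10 kb beyond the footprint had 664 ± 62.9. The near flank held 2.99 ± 0.19 and the far flank 9.20 ± 0.40 times the reads expected at their distance, by a curve fitted without them. At these distances that curve rested mostly on the other side, so these ratios largely repeat the comparison with mirror positions below. Under the curve of the peak test, fitted with the flanks, the windows at 20 to 25 kb and 25 to 30 kb, partly and wholly in the near flank, were at 1.01 and 1.09. Together the flanks held 5.03 ± 0.29 times the reads expected at their distance (SD, n = 3). The ratios were 5.34 (95% Poisson interval 5.20 to 5.48), 4.76 (4.63 to 4.90) and 4.98 (4.83 to 5.13) in the 3 columns. The density of the far flank was 1.49-fold to 1.51-fold that of the near flank over the columns, although it lay farther from the viewpoint. Capping the fragment counts lowered the ratio to 2.59. A power law as expectation gave 8.88, and placing the viewpoint at the midpoint or at the other unlisted stretch gave 8.07 and 10.3. These distances are in reference coordinates. If the footprint is deleted, the far flank lies 6694 bp nearer to the viewpoint in these cells. With the footprint length taken out of distances, the ratio of both flanks together was 4.12, and the single flanks were not recomputed.

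Next to the footprint, clusters of fragments were delimited by their own counts, as consecutive fragments with at least 100 reads, so their densities are described and not tested. On the viewpoint side, 4 fragments at 111007026 to 111009073 had a density of 1257 ± 164 (SD, n = 3). On the far side, 15 fragments at 111016072 to 111022003 had a density of 997 ± 112 and held 5.91% ± 0.67 of all cis reads. The sequence between the viewpoint and the near flank, 110977139 to 110999377, had a density of 285 ± 15. In the gene order of GRCm38, the embryonic genes Hbb-bh1 and Hbb-y lie between the adult globin genes and the LCR. Over their full 10 kb, the near flank had 1.55-fold the density of that intervening sequence (range 1.46 to 1.59 over the columns), and the far flank had 2.32-fold (2.21 to 2.39). Beyond the far flank the density dropped to 105 ± 9.41 over the next 10 kb, so that the far flank was 6.30-fold higher (6.12 to 6.51).

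**Figure D1:**
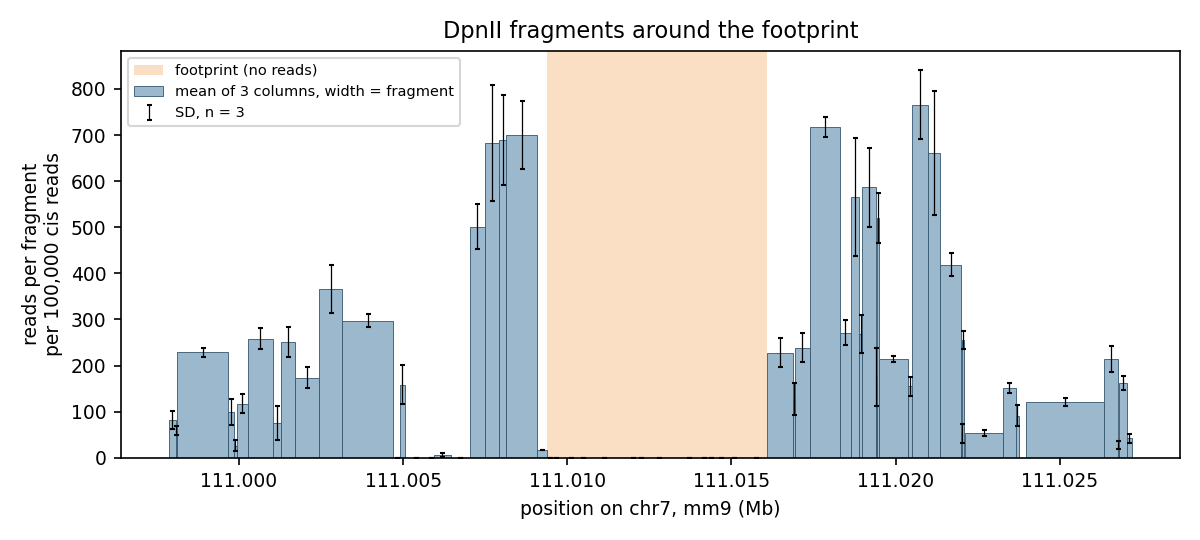
Reads per DpnII fragment per 100000 cis reads (y axis) against position on chr7 in mm9 (x axis, Mb), as the mean of 3 columns with SD and with each bar as wide as its fragment. The 14 fragments of the shaded footprint have 0 reads, between a cluster of 4 fragments on the left and one of 15 fragments on the right.

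The second comparison set the LCR side against the other side of the viewpoint at the same distances. It is an internal control for the effect of distance only if the single viewpoint position holds. Between 5 and 100 kb, the LCR side held 2.64-fold the reads of the other side (log2 ratio 1.40 ± 0.018, SD, n = 3), with 2.68-fold, 2.63-fold and 2.61-fold in the 3 columns. The exact sign-flip permutation test gave p = 0.25, two-sided, which is the smallest that 3 columns allow. The near flank exceeded its mirror position by 2.72-fold (2.60 to 2.89 over the columns) and the far flank exceeded its mirror position by 11.8-fold (10.6 to 12.9). Mirror positions are in reference coordinates. If the footprint is deleted, all sequence beyond it, the far flank included, lies nearer to the viewpoint in these cells. On the other side, the 5 kb windows from 30 to 50 kb held 871, 864, 436 and 238 reads, so a nearer mirror position would lower the 11.8-fold. The comparison of sides was not recomputed for that case. Without both flanks, the footprint between them and the mirror positions of all of these, the log2 ratio was 0.87. The footprint had 0 reads, so leaving it and its mirror out took reads only from the other side, which raises this ratio. With the other unlisted stretch as viewpoint the log2 ratio was 2.48.

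The order of the sides changed with distance. At 1 to 5 kb the other side was 3.19-fold higher, with 2080 ± 315 against 649 ± 63.8. At 30 to 50 kb the densities were 461 ± 48.2 on the LCR side and 88.3 ± 2.22 on the other side. At 75 to 100 kb they were 80.7 ± 6.73 and 15.5 ± 1.01, and at 100 to 150 kb they were 34.6 ± 2.58 and 8.42 ± 0.14. At 150 to 200 kb the order turned, with 7.18 ± 0.87 on the LCR side and 10.6 ± 1.25 on the other side. At 5 to 10 kb the other side held 3.18 ± 2.35, where a run of 20 fragments without reads lay, against 238 ± 6.84. At 10 to 20 kb the other side was higher, with 251 ± 39.8 against 197 ± 15.6. Of its 3402 reads there, 2816 lay at 15 to 20 kb, on the outer side of the other unlisted stretch, which may be a second viewpoint. The fragment adjoining that stretch on its outer side held only 14 reads, and the one on its inner side held 268. The fragments adjoining the viewpoint stretch held 2188 and 573 reads. At 1 to 2 Mb the other side was 2.79-fold higher, with 6.52 ± 0.14 against 2.34 ± 0.083, and 1.81-fold higher per listed fragment. At 5 to 10 Mb the LCR side was higher, with 1.02 ± 0.051 against 0.678 ± 0.050, and 1.17-fold higher per listed fragment. At 10 to 20 Mb the densities were 0.704 ± 0.061 and 0.487 ± 0.026, with 5773 listed fragments on the LCR side and 3880 on the other side, and the order did not hold per listed fragment, with 1.66 and 1.72 reads. In the GRCm38 order, olfactory receptor genes flank the globin genes on both sides, beginning with Olfr66 beyond the LCR and with Olfr67 beyond the adult globin genes.

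**Figure D2:**
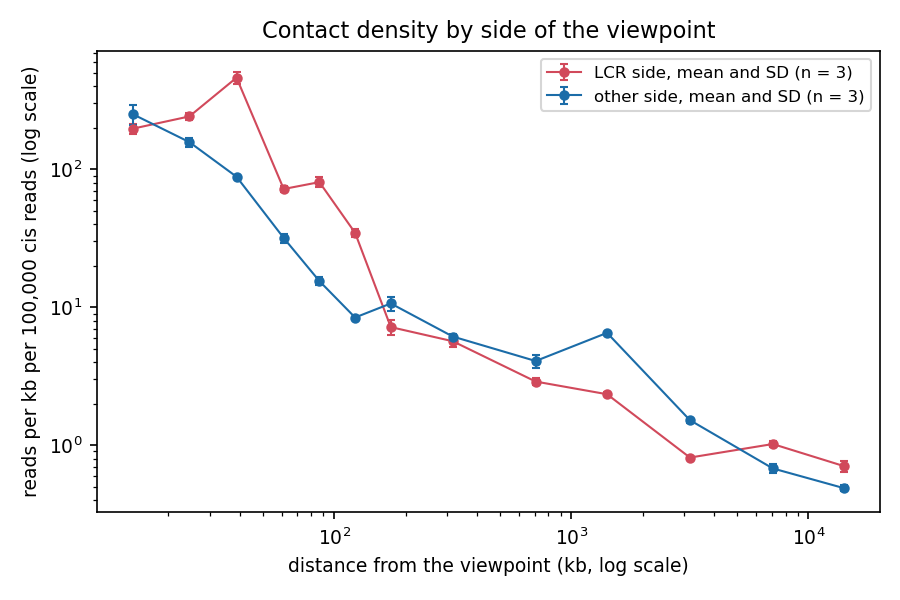
Contact density in reads per kb per 100000 cis reads (y axis, log scale) against distance from the viewpoint (x axis, kb, log scale) from 10 kb to 20 Mb, with mean and SD over 3 columns for each side. The LCR side lies above the other side from 20 to 150 kb and beyond 5 Mb, and below it at 10 to 20 kb and from 150 kb to 5 Mb; per listed fragment it is not higher at 10 to 20 Mb (1.66 against 1.72 reads).

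The third question was how contacts fell with distance. Reads within 100 kb made up 36.6% ± 3.38 of the cis reads (SD, n = 3), and reads within 1 Mb made up 46.6% ± 2.77. The share within 100 kb was 39.0% (95% exact binomial interval 38.6 to 39.5) in the first, 32.7% (32.3 to 33.1) in the second and 38.0% (37.5 to 38.5) in the third column, so the columns differed by more than counting error. From 5 kb to 10 Mb the density fell with a log-log slope of -0.88 ± 0.017 (SD, n = 3). The bootstrap interval of the summed profile was -1.0 to -0.78. The slope depended on the measure and range by more than this SD: it was -0.73 per fragment and -1.10 from 20 kb to 2 Mb. The listed share of the sequence falls with distance, so part of the fall per kb may come from unlisted fragments.

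The fourth question was where contacts exceeded the distance expectation. Of 396 windows between 10 kb and 1 Mb, the negative binomial test called 0 after Benjamini-Hochberg adjustment, and 9 had an unadjusted p under 0.05. These 9 are a smaller share of the windows than the 0.05 that chance alone would give in an exact test. The smallest adjusted p was 0.77, at a dispersion of 1.37. With the expectation taken from the side away from the LCR, 2 windows were called, and with a power law 1 was. By a fold rule chosen after seeing the data, 17 windows in 11 regions were at least 2-fold over expectation in every column.

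The window 40 to 45 kb from the viewpoint on the LCR side, 111016215 to 111021215, in the far flank, held 4.79 ± 0.24 times its expected reads (SD, n = 3). On the same side, 111056215 to 111061215 held 4.34 ± 0.42 times, within a region of 75 to 85 kb that held 3.53 ± 0.19 times. Farther out, 111391215 to 111396215 held 5.06 ± 0.60 times and 111496215 to 111501215 held 4.63 ± 0.39 times. On the other side, 110106215 to 110111215 held 5.64 ± 1.13 times. With the expectation from the side away from the LCR, the ratio of the far-flank window was 16.4 and that of the window at 111056215 was 11.9, and with a power law that of the far-flank window was 18.4. The power law also raised the window at 111056215 to 5.59. Some alternatives lowered a ratio, to 3.43 for the far-flank window with capped fragments, to 3.36 and 3.45 for the windows at 111391215 and 111496215 with a power law, and to 3.92 for the window at 110106215 with the other side as expectation. Close to the other unlisted stretch, the 10 kb on its outer side had a density of 274 ± 36.2, with the most reads, 959, in the fragment 110957505 to 110958539.

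**Figure D3:**
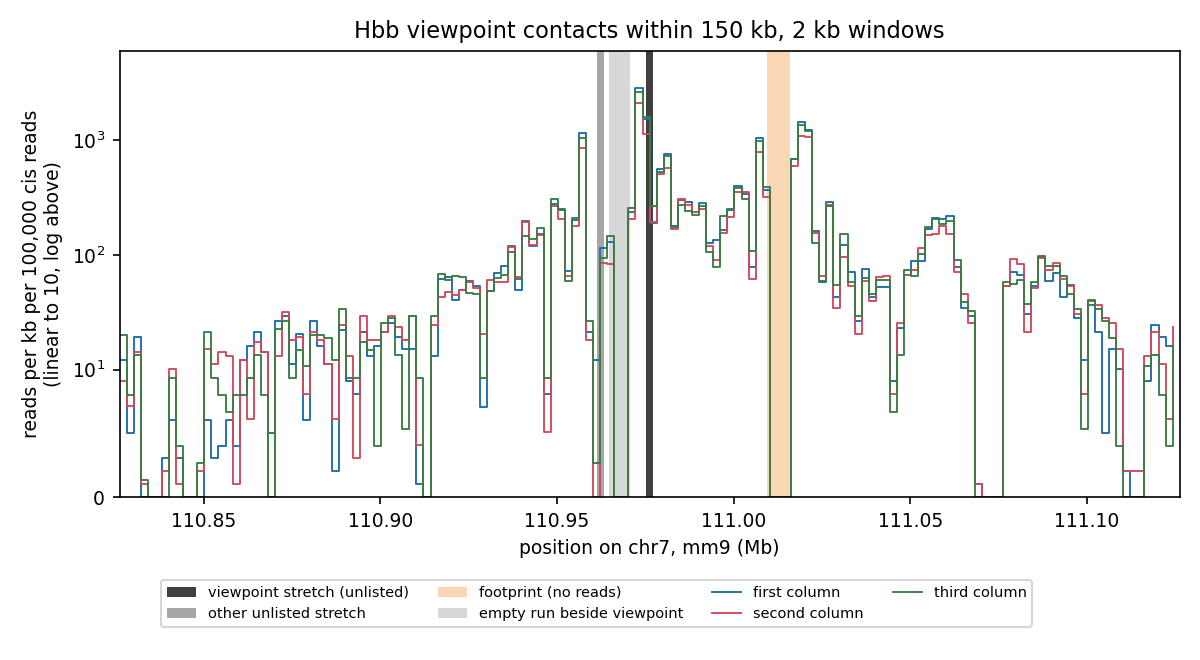
Reads per kb per 100000 cis reads in 2 kb windows (y axis, linear to 10 and log above) against position on chr7 in mm9 (x axis, Mb), with 1 line per column within 150 kb of the viewpoint. Shading marks the unlisted stretches and the runs without reads, and the 3 columns share their peaks on both sides of the footprint.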

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

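The tests of recurring fragment lengths and of the neighbours of the isolated fragment were chosen before their results were seen, and the other tests in this part after.

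For the footprint of 14 empty fragments, chance at this depth is argued against by the 6877 reads that its flanks predict and the 1122 that its distance predicts. Repeat sequence that cannot be mapped uniquely cannot be told apart: 0% of its 13 pairs of neighbouring fragment lengths recur along the chromosome, but only 1 of 74 other empty pairs within 1 Mb recurred, against 5 of 2344 pairs with reads (Fisher's exact p = 0.17, two-sided), so the test had almost no power. The run is 100% listed in a list that thins with distance, a value looked at after that test failed, and it excludes nothing because how the list was made is not stated. The deletion in the labels remains a candidate explanation, with 0 reads where the flanks predicted at least 2007 and distance at least 310 in each column, untested against a library without the deletion. Runs of 5913, 5854 and 5297 listed bp without reads also occur within 1 Mb where no deletion is named, with 123, 46.0 and 36.6 reads predicted by distance and 60.3, 4.05 and 6.45 by their flanks.

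A second run of 20 fragments without reads lay beside the viewpoint, at 110964839 to 110970616, between the unlisted stretches. Its flanks predict 6863 reads and its distance 1502, which argues against chance. Repeat sequence stays open, since 7.14% of its 14 pairs of fragment lengths recurred in the same test without power, and 90.4% of the run is listed. Likeness to the viewpoint or its copy, with reads discarded upstream, cannot be told apart from sequence that these mice of mixed strain lack: the sequence of the run was not used, and the 552 unlisted bp inside it decide nothing. A strain difference may therefore be open as a biological explanation and was not tested.

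One fragment far beyond the range of the comparisons stood out as a signal in data that no comparison used. The 148 bp fragment at 147659332 to 147659479, 36.7 Mb from the viewpoint, had 142 reads (62, 41 and 39 in the columns), where the next highest of 29022 fragments beyond 10 Mb had 25 and a count of 0 allows 3. Amplification in one library is argued against, since no column held more than 40.1% of its scaled reads. Contact of a wider region cannot be told apart: read density within 10 kb was 0.29 times that at 10 to 500 kb, but that test is void, since 1 listed fragment with 2 reads covers 3.8% of those 20 kb, and per listed kb the values were 2.64 and 2.45 reads. Repeat sequence that cannot be mapped uniquely may be the source and stays open, since 0 listed fragments adjoin it, and no biological explanation was tested.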

How the results depend on the processing

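The fold rule, and alternatives with another viewpoint, LCR window or excluded stretch, were chosen after seeing the data. No sign changed among the results with alternatives; the values by mirror position, cluster and distal window were computed under 1 setting only, and those by distance also per listed fragment, where the order at 10 to 20 Mb did not hold (1.66 and 1.72 reads). Leaving out 1 column moved the slope to between -0.89 and -0.87, the 100 kb share to 35.4% to 38.5%, the 1 Mb share to 45.7% to 48.2%, the log2 side ratio to 1.39 to 1.41, the LCR ratio to 4.87 to 5.16 and the windows of the fold rule to 18 to 19. The footprint stayed at 6694 bp, the contact peaks at 0. By construction, leaving out a column can only keep or lengthen the longest run without reads, and keep or add windows of the fold rule. Capping fragments gave a slope of -0.85, shares of 25.8% and 37.6%, a side ratio of 1.11 and an LCR ratio of 2.59, which follows from its construction, since it lowers the fragments with the most reads. Leaving out fragments within 5 kb gave shares of 28.8% and 40.1%. Leaving out fragments under 100 bp shortened the footprint to 6603 bp. The slope was -1.10 from 20 kb to 2 Mb and -0.73 per fragment. The side ratio was 1.34 for 5 to 50 kb, 1.29 for 10 to 200 kb, 1.54 per listed fragment and 0.87 without the flanks, the footprint and their mirror positions. The LCR ratio was 8.88 with a power law, 5.48 with the other side as expectation, 4.71 and 4.10 for flanks of 5 and 15 kb, and 4.12 with the footprint taken out of distances. The 5.48 is no independent check, since the main expectation already rested mostly on the other side at those distances. With the other unlisted stretch as viewpoint the slope, side ratio and LCR ratio were -0.95, 2.48 and 10.3, and with the midpoint -1.01, 1.80 and 8.07. Where no construction is named, the cause was not tested. Contact peaks numbered 1 with a power law and 2 with the other side as expectation. The fold rule gave 13 to 23 windows; 14 of the 17 remained with a power law and 15 with the other side. The planned LCR windows beyond Hbb-y and all gene-based results were not run. Counts per column limit a fragment without reads to 3 reads. The spread between windows limits the peak test: 4.5% of simulated 3-fold windows were called at the fitted dispersion and 58.25% at a lower one. Unlisted fragments, counted as having no reads, enter that dispersion, and their effect on it was not tested. No paired analysis was possible because the series has 1 group.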

Other observations

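Beyond 1 Mb, single windows on both sides held more reads than their distance predicted. By the test used for contact peaks, applied to this range after seeing the data and without alternative expectations, 6 of 3600 windows of 5 kb between 1 and 10 Mb passed an adjusted p under 0.05, and 137 had an unadjusted p under 0.05. These 137 are also a smaller share of the windows than 0.05. The highest were adjoining windows 6.94 Mb away on the LCR side: 117916215 to 117921215 held 18.1 ± 1.12 times its expected reads and 117921215 to 117926215 held 18.8 ± 3.56 times (SD, n = 3; adjusted negative binomial p of 0.0022 for each). On the other side, 105321215 to 105326215 held 16.2 ± 4.61 times and 107611215 to 107616215 held 13.3 ± 3.75 times. The window with the most reads between 1 and 2 Mb on that side, 109591215 to 109596215, held 300 reads against 27.6 expected, 11 ± 1.0 times, with an adjusted p of 0.068. These p-values compare windows of 1 profile and not biological replicates. In the expectations, unlisted fragments counted as having no reads. The list covered 76.4% of the sequence at 1 to 2 Mb and 25.6% at 10 to 20 Mb. The listed share of the named windows was not computed, so how far a fuller listing raises their ratios was not tested.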
